A study of Mus musculus with 4 samples.

How the data were processed

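Skin RNA of mice was sequenced in 4 groups labelled PRP-MNs, PRP, MNs and NC, with 1 library in each group, so that no group had replicates. Whether a library came from 1 animal or several, the time of harvest and the stage of the hair cycle were not given in the sources used here. Per the labels' protocols, libraries were made from 1 μg of RNA with the NEBNext Ultra kit for Illumina. Whether strands were kept apart was not given in the sources used here, so the values of genes that overlap on opposite strands may be uncertain. The genome build was GRCm38, per the submitters' processing notes. The aligner, the quantification tool and the gene annotation were not given in the sources used here.

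The authors deposited 1 table of FPKM values per gene, fragments scaled to transcript length and library depth, with 1 column per library. It held 25571 genes, of which 3535 were gene models assembled from the reads and 22036 had Ensembl identifiers. Of these, 22022 matched GENCODE release M21, which is on GRCm38 and from which coordinates were taken. A set of 27 symbols that a spreadsheet had turned into dates was restored through the identifiers. In 4740 genes the value was 0 in every library. FPKM values are scaled within a library, so a few abundant genes can shift all others. The FPKM sum differed between libraries, at 460805 in PRP-MNs, 500187 in PRP, 448607 in MNs and 515230 in NC. Mitochondrially encoded genes took 12.6%, 15.5%, 10.9% and 13.7% of these sums, and the 50 most abundant genes of each library took 23.7%, 29.6%, 22.8% and 31.2%.

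Depth was estimated from the steps between low values of genes with a single annotated transcript, where 1 fragment is worth a fixed amount divided by the transcript length. In PRP-MNs, PRP, MNs and NC, 24.5%, 27.6%, 24.0% and 23.8% of low values lay within 0.02 of a whole number of fragments at the best step, against medians of 2.87%, 2.62%, 2.86% and 2.86% at other steps. Whole fragments could not be recovered for most genes, and no count test was run. The steps gave about 17.2, 15.9, 18.6 and 19.3 M fragments, in the same order. Taking 3 fragments as the floor, a transcript of 1 kb was at 0.174, 0.188, 0.161 and 0.155 FPKM. These floors cover counting error only.

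The comparisons, list members, thresholds, named gene rule and alternatives were chosen before the data were examined, except where stated. The 5 comparisons were PRP-MNs, PRP and MNs each against NC, and PRP-MNs against PRP and against MNs. A gene was tested where it reached 1 FPKM in at least 1 of the 2 libraries, and its difference was log2 of the ratio of FPKM + 1. A difference of at least 2-fold on that scale was counted. With 1 library per group no p-value or error between animals could be given. The named genes were the 10 highest and 10 lowest of PRP-MNs against NC and the 5 highest and 5 lowest of each other comparison, among genes at or above 5 FPKM in at least 1 of the 2 libraries and leaving out predicted, mitochondrial and antigen receptor genes. From each list up to 4 members with the largest difference could be named, and 15 hair growth signalling genes and the Y-linked genes were named whatever their values. Il36a was found under its older symbol Il1f6.

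There were 39 gene lists, which covered hair follicle compartments, epidermis, glands, fat, muscle, vessels, stroma, platelets, blood and immune cells, signalling and stress genes, and mitochondrial and ribosomal genes. A total of 8 list members were not analysed here. The values of 1 further gene are not reported here. A further 2 lists, of genes shared by leukocytes and by epithelia, were written for later tests before their values were seen, and 6 more lists were written after the data had been seen. A list's median over its measured members was set against 10000 random lists of the same size drawn from the same 20 bins of mean expression, and a percentile below 2.5 or above 97.5 was counted as apart. Lists with fewer than 3 measured members were not compared with random lists. The B cell list had at most 1 measured member (Jchain, 1.73 FPKM in MNs). For the layout with and without each treatment, 2 differences without a shared library were correlated across genes, and the overlap of independent lists was the product of both counts divided by the genes tested.

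The calculations were tested on simulated data in which 200 genes were changed 4-fold with a log2 spread of 0.1. All changed genes were recovered in each of the 5 comparisons (100%). Among 12927 genes simulated for PRP-MNs against NC, 3 unchanged genes were called, and 1 or 2 in each other comparison. Of 200 unchanged lists, 7.0%, 4.5%, 1%, 5.5% and 4% fell outside the central range in the 5 comparisons, where 5% would by chance. The simulation held no difference between animals or pieces of skin, and its unchanged lists were of unrelated genes. It therefore checked the calculations only, and its rates are not error rates of the counts and list calls reported here. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, thresholds of 1.5-fold and 4-fold, protein-coding genes alone, a common sum per library with and without hair, epidermal and muscle genes, and centring on the median of all genes. Annotated genes alone and a common sum without mitochondrial genes were added after the data had been seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.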

Results

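RNA was sequenced from the skin of mice in 4 groups, with 1 library per group. The groups are labelled PRP-MNs, PRP, MNs and NC. Platelet-rich plasma (PRP) is the platelet concentrate of blood, which carries growth factors, and microneedles (MNs) are arrays of fine needles that carry a substance into the skin. The labels do not spell out NC, which was used as the reference. The values were FPKM, fragment numbers scaled to transcript length and to the depth of the library. Steps in the low values corresponded to about 17.2 M fragments in PRP-MNs, 15.9 M in PRP, 18.6 M in MNs and 19.3 M in NC. An FPKM of 1 on a transcript of 1 kb was thus about 15.9 to 19.3 fragments, and 3 fragments lay between 0.155 FPKM in NC and 0.188 FPKM in PRP, limits that cover counting error only. Genes at or above 1 FPKM numbered 13210 in PRP-MNs, 13145 in PRP, 13386 in MNs and 12702 in NC. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in every library, with Ddx3y between 21.1 FPKM in MNs and 29.6 FPKM in NC.

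The series title concerns hair regrowth with microneedles loaded with platelet-rich plasma, and the group names form a layout with and without PRP and with and without MNs. Across 14475 genes, the libraries closest to each other were PRP and NC (Pearson r = 0.950 on the log2 scale) and the farthest apart were PRP-MNs and NC (r = 0.800). These correlations are across genes, which are not independent replicates. With 1 library per group no difference has a replicate check, no p-value was computed, and each value describes these libraries rather than the treatments. PRP-MNs, PRP and MNs were all set against the same NC library. A list higher or lower in each of them may therefore reflect that library alone. Log2 differences are of FPKM + 1, which understates the difference of low genes. A gene list is called above or below random lists where its median lay outside the central 95% of 10000 lists of the same size matched on expression.

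PRP-MNs was compared with NC to ask how skin that received the combined treatment differed from the reference. Among the lists fixed in advance, genes of inflammation and of the interferon response were the most strongly higher, and genes of epidermal differentiation the most strongly lower. Slfn4, a Schlafen family gene of myeloid cells, stood at 663 FPKM in PRP-MNs and 0.86 FPKM in NC, a log2 difference of 8.48. Cxcl5, a chemokine that attracts neutrophils, stood at 244 FPKM in PRP-MNs and was listed at 0 in NC. Ankrd1, a stress-responsive ankyrin repeat gene, was at 450.0 against 1.46 FPKM. The monocyte surface gene Ly6c2 was at 651 against 2.81 FPKM, the chitinase-like gene Chil3 at 274 against 0.61 FPKM, and Ms4a4c at 231 against 0.50 FPKM. The other genes among the 10 highest were the antiviral gene Rsad2 (201 against 0.73 FPKM) and the chemokines Cxcl10 (303 against 1.91 FPKM), Ccl4 (142 against 0.43 FPKM) and Ccl3 (174 against 0.77 FPKM).

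On GRCm38, Slfn4 (ENSMUSG00000000204) lies on chromosome 11 from 83175186 to 83190216 and Ccl3 (ENSMUSG00000000982) on the same chromosome from 83647844 to 83649355. Cxcl5 (ENSMUSG00000029371) lies on chromosome 5 from 90759360 to 90761624 and Cxcl10 (ENSMUSG00000034855) on chromosome 5 from 92346638 to 92348889. Ly6c2 (ENSMUSG00000022584) spans chromosome 15 from 75108158 to 75111970. Rsad2 (ENSMUSG00000020641) spans chromosome 12 from 26442746 to 26456452. Of the lower genes, Ereg (ENSMUSG00000029377) lies on chromosome 5 from 91074622 to 91093646, Krt77 (ENSMUSG00000067594) on chromosome 15 from 101858731 to 101869705, and Lor (ENSMUSG00000043165) on chromosome 3 from 92080271 to 92083142. Slfn4, Ly6c2, Ccl3, Ccl4 and Serpinb3a belong to families of related genes, and their values are uncertain where fragments could be split between members.

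Among 18 interferon-stimulated genes, 17 were at least 2-fold higher in PRP-MNs, and the list median was 4.66 on the log2 scale. Rsad2, Cxcl10, Isg15 and Ifit1 differed by 6.86, 6.71, 6.21 and 6.11. Of 15 measured inflammatory cytokines and chemokines, 13 were at least 2-fold higher, with a median of 3.96. The monocyte attractant Ccl7 was at 504 against 4.55 FPKM. The only one at least 2-fold lower was Il1f6, which encodes the epidermal cytokine IL-36 alpha (7.15 against 157 FPKM). All 7 measured neutrophil genes were higher (median 2.99), among them the receptors Csf3r (89.5 against 0.74 FPKM) and Cxcr2 (59.4 against 6.58 FPKM). Of 14 macrophage genes, 11 were at least 2-fold higher (median 2.20), led by the Fc receptor Fcgr1 at 142 against 0.70 FPKM. All 12 genes shared by leukocytes in general were also higher, with a median of 3.37. The T cell list lay within the random range (median −0.67), with Cd3g at 3.91 against 17.1 FPKM, but below it with a pseudocount of 0.1 (percentile 2.18) and after rescaling without mitochondrial genes (percentile 2.42). In the Langerhans and dendritic cell list (median 0.11), Cd207, the langerin gene of Langerhans cells, was at 0.97 against 23.3 FPKM.

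All 19 measured genes of epidermal differentiation were at least 2-fold lower in PRP-MNs, with a median of −3.08. Loricrin (Lor), a main protein of the cornified envelope, was at 61.1 against 1058 FPKM, Flg2 at 8.93 against 167 FPKM, Krtdap at 497 against 6947 FPKM and the suprabasal keratin Krt10 at 475 against 6056 FPKM. Krt77 was at 132 against 2482 FPKM, and the growth factor gene Ereg, a ligand of the EGF receptor, at 4.81 against 121 FPKM. The remaining genes among the 10 lowest were Rarres1 (4.60 against 108 FPKM), Defb6 (3.51 against 84.1 FPKM), Bbox1 (1.55 against 43.4 FPKM), Calm5 (7.67 against 149 FPKM) and Serpinb3a (0.83 against 30.6 FPKM). Basal keratinocyte genes were lower by less (median −0.85), with Krt5 at 689 against 2348 FPKM. Genes shared by epithelia in general had a median of −1.89, and 11 of 12 were at least 2-fold lower. Wound-associated keratinocyte genes were above random lists (median 0.65, 4 of 12 at least 2-fold higher), with the cytokine gene Il24 higher by 3.82 and Krt6a at 1325 against 646 FPKM. That list shares S100a8 and S100a9 with the neutrophil list, so it is not a measure of keratinocytes alone. Ribosomal protein genes were also lower, with a median of −1.01. That list was taken by symbol prefix and holds 10 ribosomal S6 kinase genes. Without them the median was −1.02 and 52 of 89 genes were at least 2-fold lower.

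Vascular and stromal genes were higher in PRP-MNs than in NC. Of 17 measured genes of blood vessel endothelium and angiogenesis, 16 were at least 2-fold higher (median 2.42). Apelin (Apln), a peptide of sprouting vessels, was at 24.3 against 0.28 FPKM, the endothelial adhesion gene Pecam1 at 79.1 against 6.83 FPKM, and Angpt2 at 12.1 against 0.34 FPKM. Matrix metalloproteinases and their inhibitors had a median of 1.76, with Timp1 at 139.6 against 3.89 FPKM and the collagenase gene Mmp13 at 49.1 against 5.75 FPKM. Medians also lay above random lists for smooth muscle and pericytes (1.38), Schwann cells and nerve (1.34), red cells (1.27), adipocytes (0.88) and fibroblasts and extracellular matrix (0.67). In the fibroblast list Thbs1, a matricellular protein that platelets also release, was at 477 against 27.6 FPKM. Growth factors carried by platelets and their receptors had a median of 0.83, with Pdgfra at 45.6 against 4.75 FPKM and Fgfr2 at 3.88 against 30.8 FPKM. Of 10 platelet genes, 3 were measured, with a median of 3.38, which was 0.17 without a filter on low values. The chemokine genes Pf4 (236 against 21.7 FPKM) and Ppbp (56.1 against 0.31 FPKM) were higher and the integrin gene Itga2b differed by 0.17. The platelet list also lay above random lists in MNs against NC (median 2.42), so it is not particular to the PRP groups.

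Hair follicle genes did not share a direction between PRP-MNs and NC. Inner root sheath genes were lower (median −1.13), as were hair matrix and lineage regulators (median −1.44), in which Sox21 was at 1.18 against 11.3 FPKM and Runx1 was higher at 25.6 against 1.83 FPKM. Of 13 inner root sheath genes, 2 reached 10 FPKM in any library, the highest being Gata3 (37.6 FPKM), so that list rests mostly on low genes. Against NC 7 of them were measured, but in PRP-MNs against PRP only 2. Most of the 7 thus passed the filter only through NC, which favours a lower median in PRP-MNs. Without a filter on low values the list still lay below random lists. Wnt targets and modulators had a median of −0.92, with Dkk3 at 1.70 against 5.97 FPKM. With a filter at 5 FPKM the Wnt list lay at percentile 3.60, within the random range. Dermal papilla genes were higher (median 1.41), with Inhba at 10.1 against 0.42 FPKM and Vcan, which monocytes also express, at 45.3 against 1.33 FPKM. Follicle stem cell genes had a median of −0.00, with Krt15 lower (12.6 against 78.3 FPKM) and Tcf7l1 higher (4.95 against 1.54 FPKM). Sebaceous gland genes were lower (median −2.13). The wax synthesis gene Far2 was at 1.23 against 22.5 FPKM, whereas the lipid droplet gene Plin2, also expressed in macrophages, was at 234 against 21.7 FPKM. Cell cycle genes had a median of −0.51, and 3 of 27 were at least 2-fold lower. Most hair shaft genes were below 1 FPKM in every library. The keratin Krt84 was the only one of 14 hair shaft keratins to reach 1 FPKM in any library (5.47 FPKM in NC), and 2 of 56 keratin-associated protein genes did so, with Krtap3-2 at 6.85 FPKM in NC.

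Of 13981 genes tested between PRP-MNs and NC, 2462 were at least 2-fold higher and 1607 at least 2-fold lower. Centred on the median of all genes, 2061 were higher and 1933 lower, a share of higher genes of 51.6% in place of 60.5%. Of 35 lists with at least 3 measured members, 15 lay above and 8 below random lists. The remaining lists lay within the random range, among them immediate early genes (median 0.21), heat shock genes (−0.29), mitochondrially encoded genes (−0.34), skeletal muscle (0.27), melanocytes (1.01), mast cells (0.58), lymphatic endothelium (0.07) and follicle rest signals (0.48). With a filter at 5 FPKM the lymphatic median was −1.18, below random lists (percentile 1.71). Rescaling every library to the same sum moved the median of all genes upward by 0.16, and the random lists moved with it. In the mast cell list the histidine decarboxylase gene Hdc was at 119 against 1.39 FPKM, and in the lymphatic list Pdpn was higher by 4.39 while the lymphatic chemokine Ccl21a was at 0.96 against 13.7 FPKM.

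**Figure D1:**
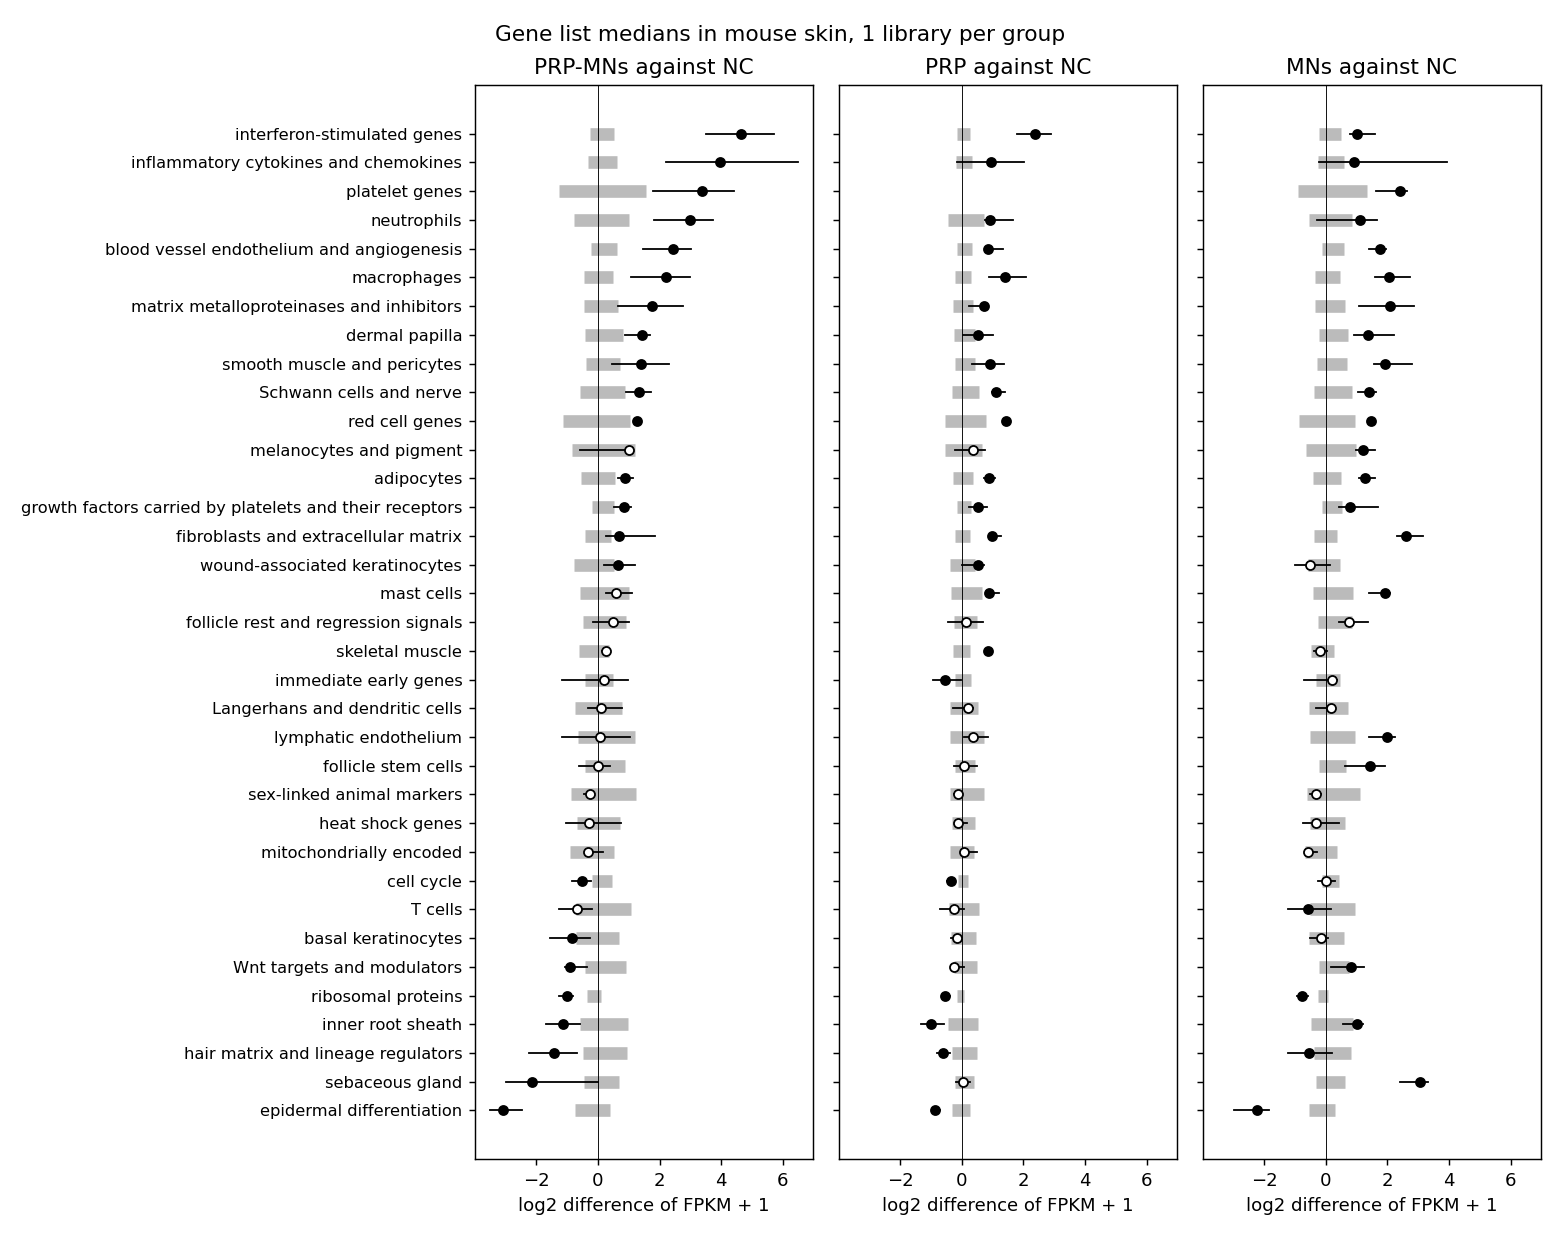
Median log2 difference of each gene list against NC for PRP-MNs, PRP and MNs (x axis, log2 of FPKM + 1), with lines for the quartiles of the list members and grey bars for the central 95% of medians of 10000 random lists. Filled points lie outside the grey bars, as for interferon-stimulated genes (4.66, 2.37 and 1.03) and epidermal differentiation (−3.08, −0.85 and −2.22).

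**Figure D2:**
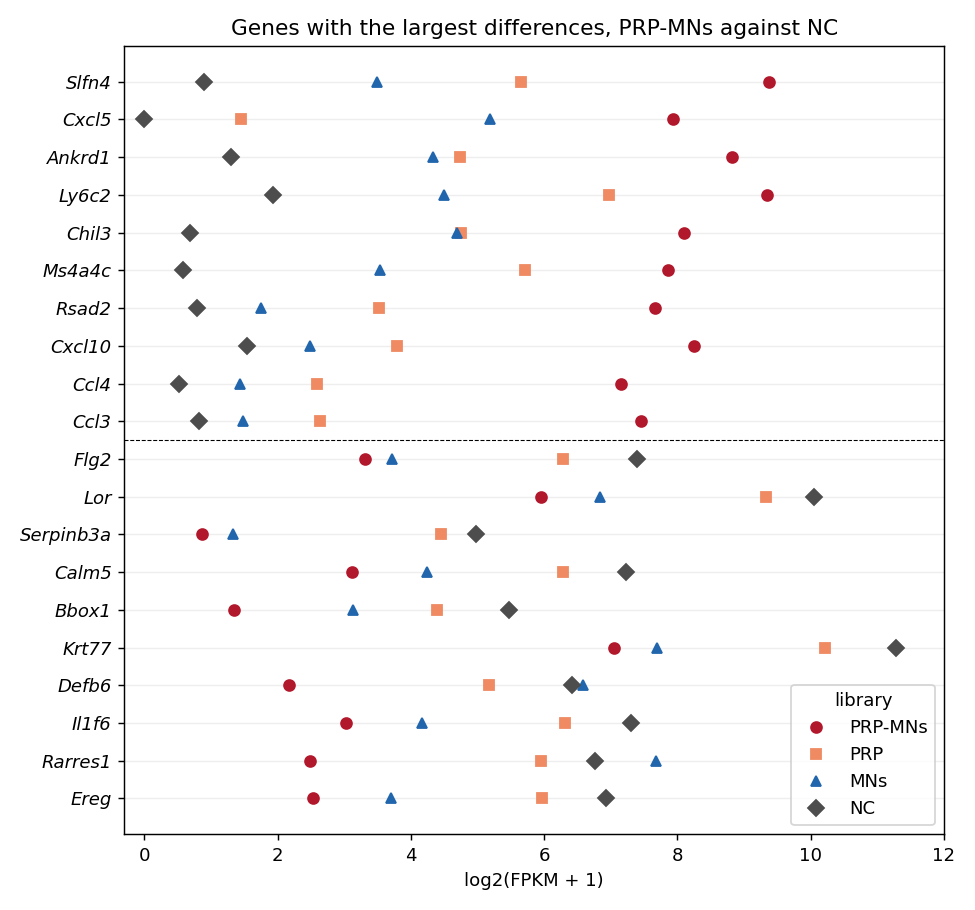
Expression of the 10 most strongly higher and the 10 most strongly lower genes of PRP-MNs against NC in each library, as log2(FPKM + 1), 1 point per library. Slfn4 stands at 663 FPKM in PRP-MNs and 0.86 FPKM in NC, and Ereg at 4.81 and 121 FPKM.

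Genes tied to hair growth signalling were read in all 4 libraries. Beta-catenin (Ctnnb1), the transducer of Wnt signals, was at 111 FPKM in PRP-MNs, 105 FPKM in PRP, 167 FPKM in MNs and 127 FPKM in NC. The Wnt ligand gene Wnt3a was at 1.60 FPKM in PRP-MNs, 2.64 FPKM in PRP and 2.04 FPKM in MNs and differed by −0.94 between PRP-MNs and NC, and Wnt10b was below 1 FPKM except in NC, where it was at 1.75 FPKM. Lef1 was below 1 FPKM in every library. Sonic hedgehog (Shh) was at 2.28 FPKM in PRP-MNs and 0.13 FPKM in MNs, and was listed at 0 in PRP and NC. The vascular growth factor gene Vegfa was at 12.6, 12.3, 10.4 and 6.45 FPKM in PRP-MNs, PRP, MNs and NC. Igf1 was at 9.97, 11.7, 18.5 and 5.29 FPKM, and Fgf7, a growth factor of the dermal papilla, at 10.9, 6.76, 20.5 and 2.72 FPKM. Pdgfa was at 11.8, 8.38, 6.68 and 5.27 FPKM and Pdgfb at 9.94, 7.37, 6.70 and 7.01 FPKM. Of the genes linked to follicle regression, Tgfb1 was at 51.3, 17.6, 35.0 and 10.1 FPKM, Tgfb2 at 2.44, 2.77, 6.20 and 1.36 FPKM, and Fgf5 at 1.03, 0.11, 0.23 and 0.02 FPKM. Bmp4 was at 2.37, 3.98, 5.34 and 5.96 FPKM. The proliferation marker Mki67 was at 8.58, 12.1, 17.5 and 17.4 FPKM. The hedgehog target Ptch1, a readout of Shh signalling, was at 3.51 FPKM in PRP-MNs and 2.58 FPKM in NC.

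PRP was compared with NC to ask what skin given PRP without microneedles showed. Saa3, an acute-phase gene of inflamed tissue, was at 501 FPKM in PRP and 4.40 FPKM in NC, a log2 difference of 6.54. Ms4a4c (51.3 against 0.50 FPKM), Ly6c2 (125 against 2.81 FPKM) and Slfn4 (49.3 against 0.86 FPKM) were again among the 5 highest, with Prg4, the gene of the lubricant lubricin, at 38.0 against 1.04 FPKM. All 18 interferon-stimulated genes were at least 2-fold higher in PRP (median 2.37), among them Ifit3 (54.0 against 3.53 FPKM), Isg15 (67.5 against 4.77 FPKM) and Irf7 (111 against 9.98 FPKM). Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46711998 to 46715700.

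Of 14 macrophage genes, 10 were at least 2-fold higher in PRP than in NC (median 1.41), with Fcgr1 at 27.5 against 0.70 FPKM. All 12 genes shared by leukocytes were higher (median 1.87). Inflammatory cytokines and chemokines had a median of 0.96, and 6 of 14 were at least 2-fold higher, led by Ccl7 (log2 difference 3.20) and Ccl5 (9.79 against 0.67 FPKM). Neutrophil genes had a median of 0.92 and mast cell genes 0.89. Red cell genes were higher by 1.42 in the median, with the globin gene Hbb-bs at 612 against 223 FPKM. Stromal lists lay above random lists, with medians of 0.98 for fibroblasts and extracellular matrix, 0.90 for smooth muscle and pericytes, 0.87 for adipocytes, 0.84 for blood vessel endothelium, 0.71 for metalloproteinases and 1.11 for Schwann cells. Timp1 was at 72.0 against 3.89 FPKM and Lox, which cross-links collagen, at 34.3 against 7.85 FPKM. Skeletal muscle genes were higher in PRP (median 0.85), with nebulin (Neb) at 111 against 36.7 FPKM, and 3 of 20 were at least 2-fold higher.

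Lower genes in PRP were fewer and differed by less. The metallothionein gene Mt4 was at 3.79 against 25.8 FPKM, Fosb at 6.71 against 31.2 FPKM and Retnla, a gene of alternatively activated macrophages, at 31.0 against 127 FPKM. Amd2 (1.19 against 7.68 FPKM) and Skint2 (1.04 against 6.34 FPKM) completed the 5 lowest. Epidermal differentiation genes had a median of −0.85, and 2 of 19 were at least 2-fold lower, Krtdap at 2710 against 6947 FPKM and Flg2 at 76.8 against 167 FPKM. Immediate early genes (median −0.56), inner root sheath genes (−0.99), hair matrix regulators (−0.60), cell cycle genes (−0.34) and ribosomal protein genes (−0.54) lay below random lists. Most measured inner root sheath genes again passed the filter only through NC. Sebaceous gland genes (0.02), follicle stem cell genes (0.08) and Wnt targets and modulators (−0.24) lay within the random range. Above random lists were dermal papilla genes (0.53, 3 of 10 at least 2-fold higher) and wound-associated keratinocyte genes (0.52, 1 of 11). Of 13533 genes, 1053 were at least 2-fold higher and 197 lower, centring gave 978 higher and 240 lower, and a pseudocount of 0.1 gave 1644 higher and 432 lower. Across 34 lists, 16 lay above and 6 below random lists.

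MNs was compared with NC to ask what skin given microneedles without PRP showed. Genes of the dermal matrix and of the sebaceous gland were higher, and genes of the cornified epidermis were lower. The collagen genes Col1a1 (1589 FPKM in MNs and 120.3 FPKM in NC) and Col1a2 (1796 against 156 FPKM) differed by 3.71 and 3.52, and Tnc, a matrix protein of wounds, was at 112 against 6.17 FPKM. Of 19 fibroblast and matrix genes, 18 were at least 2-fold higher (median 2.61). All 12 sebaceous gland genes were at least 2-fold higher (median 3.05), including the lipid synthesis genes Far2 (249 against 22.5 FPKM), Awat1 (log2 difference 3.35) and Fa2h (228 against 21.9 FPKM). Far2 (ENSMUSG00000030303) lies on chromosome 6 from 148047259 to 148182758.

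The highest single genes in MNs against NC were Cpxm1, a carboxypeptidase-like gene of the matrix (143 against 1.65 FPKM), Saa3 (277 against 4.40 FPKM), Cxcl5 (35.6 FPKM and listed at 0 in NC), Prg4 (57.8 against 1.04 FPKM) and Coch (83.1 against 1.97 FPKM). Among the lowest were Calcb, a calcitonin gene-related peptide gene (0.73 against 25.3 FPKM), Lce1l (17.2 against 243 FPKM), Skint9 (9.48 against 134 FPKM) and Flg2 (12.1 against 167 FPKM). The fifth, a second locus named Sept2, overlaps another gene model and its value is uncertain. All 19 epidermal differentiation genes were at least 2-fold lower (median −2.22), with Lce1b at 33.3 against 387 FPKM. Basal keratinocyte genes (median −0.15) and wound-associated keratinocyte genes (−0.51) lay within the random range, although without a filter the wound-associated list lay below it (percentile 1.75). Genes shared by epithelia were lower (median −1.04). Ribosomal protein genes had a median of −0.76.

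Follicle genes were higher in MNs than in NC for several lists. Follicle stem cell genes had a median of 1.43, and 8 of 12 were at least 2-fold higher, among them Lgr5 (6.10 against 0.27 FPKM), Krt15 (313 against 78.3 FPKM) and Lhx2 (6.17 against 0.89 FPKM). Dermal papilla genes had a median of 1.37, with Crabp1 at 63.3 against 7.47 FPKM, and melanocyte genes 1.20, with the pigment enzyme gene Dct at 8.98 against 1.04 FPKM. Inner root sheath genes had a median of 1.01, with Krt71 at 9.52 against 2.15 FPKM and Krt25 at 6.06 against 1.04 FPKM. Wnt targets and modulators had a median of 0.83, led by the Wnt inhibitor gene Wif1 (7.88 against 0.39 FPKM). Hair matrix regulators were lower (median −0.55), with Dlx3 at 2.92 against 13.1 FPKM. With a filter at 5 FPKM the inner root sheath list (percentile 61.2) and the Wnt list (percentile 90.05) were within the random range. So were the Wnt list with a pseudocount of 0.1 (percentile 97.33) and the hair matrix list without a filter (median −0.18).

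Vascular, stromal and immune lists were also higher in MNs. Medians were 1.98 for lymphatic endothelium, 1.92 for smooth muscle and pericytes, 1.76 for blood vessel endothelium, 2.08 for metalloproteinases, 1.29 for adipocytes, 1.41 for Schwann cells, 1.47 for red cells and 0.80 for growth factors of platelets and their receptors. Red cell genes were higher against the same NC library in PRP-MNs (1.27) and PRP (1.42) too, as were Schwann cell genes (1.34 and 1.11). Red cell and Schwann cell genes lay within the random range in PRP-MNs against PRP and against MNs. The smooth muscle actin gene Acta2 was at 146 against 16.5 FPKM, and the lymphatic chemokine gene Ccl21a at 78.2 against 13.7 FPKM. Lyve1, also a gene of resident skin macrophages, is in the lymphatic list (33.9 against 7.84 FPKM). Macrophage genes had a median of 2.06, led by the mannose receptor gene Mrc1 (131 against 9.63 FPKM), mast cell genes 1.94, and leukocyte genes in general 1.99. Inflammatory genes had a median of 0.92, in which Il6 was at 24.9 against 0.26 FPKM, and interferon-stimulated genes 1.03, with Isg15 at 17.8 against 4.77 FPKM. Neutrophil genes had a median of 1.12 and platelet genes 2.42. Without a filter on low values these were 0.08 and 0.17, within the random range. With a filter at 5 FPKM the neutrophil list (percentile 94.8) and the Schwann cell list (percentile 96.78) were within it as well. The mean over measured neutrophil genes was lower in MNs (30.4 against 39.0 FPKM). The T cell list lay below random lists (median −0.58), with 2 of 7 genes at least 2-fold lower, Cd3g (3.21 against 17.1 FPKM) and Cd3e (1.29 against 5.33 FPKM), and Cd4 higher (1.70 against 0.23 FPKM). Of 13925 genes, 2188 were at least 2-fold higher and 991 lower. Centred on the median of all genes, 1729 were higher and 1261 lower, a share of higher genes of 57.8% in place of 68.8%. Rescaling to a common sum moved the median of all genes upward by 0.20. Of 36 lists, 21 lay above and 4 below random lists.

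PRP-MNs was compared with PRP to ask what differed when microneedles were added to PRP. Neutrophil chemoattractants and myeloid activation genes led the higher genes. Cxcl5 was at 244 FPKM in PRP-MNs and 1.74 FPKM in PRP, Cxcl2 at 305 against 6.43 FPKM, the interleukin-33 receptor gene Il1rl1 at 112 against 1.77 FPKM, the itaconate-producing enzyme gene Acod1 at 141 against 2.64 FPKM, and the chemokine gene Ppbp at 56.1 against 0.74 FPKM. The lowest were Serpinb3a (0.83 against 20.9 FPKM), Rarres1 (4.60 against 61.2 FPKM), Ereg (4.81 against 61.8 FPKM), Serpina3j (0.72 against 17.4 FPKM) and Lor (61.1 against 643 FPKM). Of 15 inflammatory genes, 12 were at least 2-fold higher (median 3.31), including Il1b (539 against 20.8 FPKM). Of 18 interferon-stimulated genes, 17 were at least 2-fold higher (median 2.08), including Mx1 (90.6 against 11.3 FPKM).

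Neutrophil genes were higher in PRP-MNs than in PRP (median 1.91), with the collagenase gene Mmp8 at 14.5 against 0.42 FPKM, and so were blood vessel genes (1.30), dermal papilla genes (0.96), metalloproteinases (0.90), immediate early genes (0.73), macrophage genes (0.70) and smooth muscle and pericyte genes (0.51). Genes shared by leukocytes had a median of 1.49. The platelet list had a median of 1.72, which was 0.02 without a filter. Epidermal differentiation genes were lower (median −2.36), with 18 of 19 at least 2-fold lower, and sebaceous gland genes were lower (median −2.06), with Elovl3 at 1.99 against 25.6 FPKM. Hair matrix regulators (−0.97), Wnt targets and modulators (−0.68), basal keratinocyte genes (−0.76), skeletal muscle genes (−0.57) and ribosomal protein genes (−0.51) also lay below random lists. Fibroblast and matrix genes (−0.14), adipocyte genes (−0.15) and follicle stem cell genes (−0.17) did not. Of 13861 genes, 1323 were at least 2-fold higher and 1039 lower, or 1176 and 1230 when centred on the median of all genes. Of 34 lists 11 lay above and 7 below random lists. Rescaling to a common sum moved the median of all genes upward by 0.12.

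PRP-MNs was compared with MNs to ask what differed when PRP was added to microneedles. Cxcl2 was at 305 FPKM in PRP-MNs and 2.36 FPKM in MNs, Ccl3 at 174 against 1.81 FPKM, Rsad2 at 201 against 2.36 FPKM, Slfn4 at 663 against 10.2 FPKM and Cxcl10 at 303 against 4.59 FPKM. The lowest were genes of sebaceous lipid synthesis and of the gland and its duct. Far2 was at 1.23 against 249 FPKM, the fatty acid elongase gene Elovl3 at 1.99 against 244 FPKM, Fa2h at 2.10 against 228 FPKM, and Krt79, a keratin of the duct, at 10.6 against 565 FPKM. Serpina3j was at 0.72 against 102 FPKM. Of 12 sebaceous gland genes, 11 were at least 2-fold lower, with a median of −4.62.

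Interferon-stimulated genes had a median of 3.37 and 17 of 18 were at least 2-fold higher in PRP-MNs than in MNs. Inflammatory genes had a median of 2.51 (12 of 15 at least 2-fold higher), neutrophil genes 2.28 (7 of 7), and leukocyte genes in general 1.44. Macrophage genes differed in both directions (median 0.30), with Fcgr1 higher (142 against 16.8 FPKM) and the scavenger receptor gene Cd163 lower (10.6 against 38.3 FPKM). Wound-associated keratinocyte genes were higher (median 0.76), with Sprr2d, 1 of a family of near-identical copies, at 44.3 against 9.35 FPKM. S100a9 (626 against 106 FPKM) and S100a8 belong to this list and to the neutrophil list. Blood vessel genes (0.50), skeletal muscle genes (0.48), immediate early genes (0.49) and mitochondrially encoded genes (0.33) lay above random lists, although 4 immediate early genes were at least 2-fold higher and 5 lower. Fibroblast and matrix genes were lower (median −1.49), with Col1a1 at 139 against 1589 FPKM and Col3a1 at 289.6 against 1983 FPKM, and 13 of 19 were at least 2-fold lower. Metalloproteinases had a median of −0.89, with Mmp2 lower (38.1 against 303 FPKM) and Mmp13 higher (49.1 against 1.40 FPKM).

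Most follicle lists were lower in PRP-MNs than in MNs. Medians were −1.65 for the inner root sheath, with Krt71 listed at 0 in PRP-MNs and at 9.52 FPKM in MNs, −1.51 for follicle stem cells, with Krt15 at 12.6 against 313 FPKM, −1.47 for melanocytes, with Dct at 0.35 against 8.98 FPKM, −1.25 for Wnt targets and modulators, −0.47 for hair matrix regulators and −0.46 for cell cycle genes. Dermal papilla genes (−0.29, with 2 of 13 at least 2-fold higher and 2 lower) and hedgehog targets (−0.71) lay within the random range, the latter below it without a filter (percentile 2.20). Most of the 9 measured inner root sheath genes passed the filter only through MNs, which favours a lower median in PRP-MNs. The melanocyte median was −0.30, within the random range, without a filter on low values. Mast cell genes (−1.08), lymphatic genes (−0.97), basal keratinocyte genes (−0.70), epidermal differentiation genes (−0.59), smooth muscle and pericyte genes (−0.52), follicle rest signals (−0.45), adipocyte genes (−0.40), growth factors of platelets and their receptors (−0.28) and ribosomal protein genes (−0.25) were also below random lists. Ccl21a was at 0.96 against 78.2 FPKM. Of 13933 genes, 997 were at least 2-fold higher and 1030 lower, or 1021 and 992 when centred. Of 36 lists 9 lay above and 18 below random lists.

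The layout allowed each treatment's difference to be read in the presence and in the absence of the other, with no library shared between the pair. Across 14475 genes, the PRP difference measured with microneedles (PRP-MNs against MNs) and without them (PRP against NC) correlated with Pearson r = 0.36 and Spearman rho = 0.27. In both, 426 genes were at least 2-fold higher, where independent lists would share 72.5, and 39 were lower, where independent lists would share 14.0. A further 80 genes were lower with microneedles and higher without them (74.9 for independent lists), 7 the other way (13.6), and 57.3% of genes shared a sign. The microneedle difference measured with PRP (PRP-MNs against PRP) and without it (MNs against NC) correlated with r = 0.54 and rho = 0.52. In both, 730 genes were at least 2-fold higher, where independent lists would share 199.98, and 539 were lower, where independent lists would share 71.1. The genes lower with PRP and higher without it numbered 98 (157 for independent lists), 13 went the other way (90.6), and 70.2% shared a sign. Interferon-stimulated genes had medians of 3.37 and 2.37 for the PRP difference with and without microneedles, and epidermal differentiation genes −2.36 and −2.22 for the microneedle difference with and without PRP. Sebaceous gland genes had medians of −2.06 and 3.05 for the microneedle difference with and without PRP, and fibroblast and matrix genes −1.49 and 0.98 for the PRP difference with and without microneedles.

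**Figure D3:**
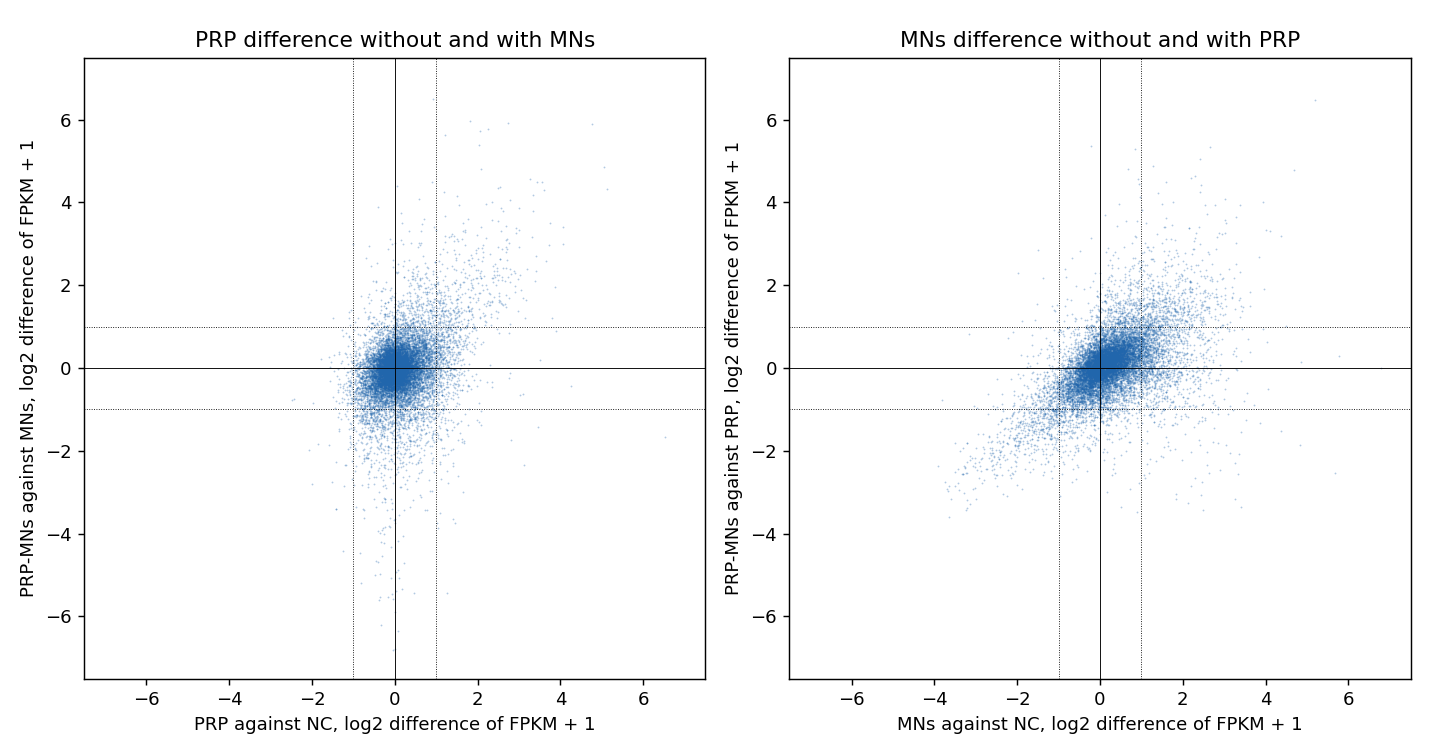
Log2 differences of 13506 annotated genes for PRP with microneedles against without them (left) and for microneedles with PRP against without it (right), 1 point per gene, with dotted lines at 2-fold. Points lie along the diagonal more closely on the right (r = 0.54 across all 14475 genes) than on the left (r = 0.36).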

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

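In this part, all tests of explanations were chosen after the result was seen. Among the fixed lists, 9 had medians of opposite sign for the same treatment difference measured with and without the other treatment, where both medians and the difference of differences lay outside the random lists. Lists with opposite signs in which a median lay within the random range are not counted here. None of these differences between groups was tested, since each group had 1 library.

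For the microneedle difference, sebaceous gland genes had a median of 3.05 without PRP and −2.06 with PRP, and the median difference of differences was −4.58. Wnt targets and modulators had medians of 0.83 and −0.68, with a difference of differences of −1.22. In MNs against NC this list lay within the random range with a pseudocount of 0.1 (percentile 97.33) and with a filter at 5 FPKM (percentile 90.05). The other lists differed for PRP without and with microneedles. Fibroblast and matrix genes had medians of 0.98 and −1.49 (difference of differences −2.48), and metalloproteinases 0.71 and −0.89 (−1.66). Mast cell genes had medians of 0.89 and −1.08 (−1.58), smooth muscle and pericyte genes 0.90 and −0.52 (−1.37), and adipocyte genes 0.87 and −0.40 (−1.32). Growth factors of platelets and their receptors had medians of 0.53 and −0.28 (−0.59), and immediate early genes −0.56 and 0.49 (0.30). The immediate early genes went both ways with microneedles, with 4 at least 2-fold higher and 5 lower, and the quartiles of their difference of differences were −0.27 and 1.14. Metalloproteinases went both ways too, with 3 at least 2-fold higher and 5 lower with microneedles, and quartiles of −2.77 and 0.62. The upper quartile of the difference of differences for mast cell genes was 0.004.

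The sebaceous gland pattern was weighed further, with Far2 at 249 FPKM in MNs, 22.5 FPKM in NC, 21.9 FPKM in PRP and 1.23 FPKM in PRP-MNs. Dilution of all skin cells by incoming cells in PRP-MNs would lower adipocyte genes alike. Their lower quartile against NC lay 2.77 above the sebaceous median. This cannot exclude dilution, since adipocyte genes were higher against the same NC library in PRP-MNs (0.88), PRP (0.87) and MNs (1.29). In PRP-MNs adipocyte genes differed by −0.15 against PRP and −0.40 against MNs, where sebaceous gland genes differed by −2.06 and −4.62. A smaller share of epithelium does not account for the whole difference between PRP-MNs and MNs. There the lower quartile of genes shared by epithelia lay 1.09 above the upper quartile of sebaceous genes. Against NC a smaller share of epithelium stays open. Genes shared by epithelia were about as low (median −1.89, with the lower quartile minus the sebaceous median of −2.13 at −0.0766), and leukocyte genes were higher (3.37). The follicle stem cell median was −0.00, but its members went both ways. Of 9 measured, 1 was at least 2-fold higher and 2 lower, Krt15 among the lower. More pilosebaceous units in the MNs skin stay open, for a part or the whole of the high values there. The lower quartile of sebaceous genes lay 0.50 above the upper quartile of follicle stem cell genes. That gap cannot decide, since FPKM + 1 understates low genes, and the stem cell genes Lgr5 and Lhx2 were below 1 FPKM in NC. Follicle stem cell (1.43), dermal papilla (1.37), inner root sheath (1.01) and Wnt target and modulator (0.83) genes were also higher, and hair matrix regulators lower (−0.55). The inner root sheath and Wnt lists lay within the random range with a filter at 5 FPKM. So did the Wnt list with a pseudocount of 0.1 and the hair matrix list without a filter. Fewer such units in PRP-MNs stay open too. The lower quartile of follicle stem cell genes lay 1.52 above the sebaceous median, but inner root sheath (−1.13) and hair matrix (−1.44) genes were lower. Most of those inner root sheath genes passed the filter only through NC, so their direction carries little weight. A difference between treatments is a further open explanation, which 1 library per group cannot separate from a difference between animals, pieces of skin or stages of the hair cycle.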

How the results depend on the processing

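No list outside the random range and no named gene at least 2-fold different reversed its direction under any alternative run, while some differences near 0 changed sign, such as Pdgfb in MNs against NC (−0.06, and 0.13 after rescaling). The count of genes depended most on the threshold. In the order PRP-MNs, PRP and MNs against NC, PRP-MNs against PRP and PRP-MNs against MNs, it was 6663, 3376, 5817, 4906 and 4030 at 1.5-fold and 1359, 191, 737, 467 and 517 at 4-fold, by construction. For PRP against NC a pseudocount of 0.1 gave 2076 genes, since it widens the differences of low genes. All other counts stayed within 1.5 times of those reported. The setting without a filter could add no gene, since a gene below 1 FPKM in both libraries cannot differ 2-fold with a pseudocount of 1. Of 175 list comparisons, 115 lay outside the random range. A pseudocount of 0.1 ended 1 of these calls, no filter 6 and a filter at 5 FPKM 5 of 107. The same settings put 2, 3 and 3 further lists outside the random range, and rescaling without mitochondrial genes 1. Among these, lymphatic genes in PRP-MNs against PRP, T cell genes in PRP against NC and mitochondrially encoded genes in MNs against NC lay below it. Scaling ended no call, and 1 factor per library can hardly move a percentile. Correlations across genes ranged from 0.34 to 0.40 for the PRP difference and from 0.51 to 0.57 for the microneedle difference. No paired analysis was possible because each group had 1 library. Replicate columns and intervals of whole reads were planned and not run, since there were no replicates and whole reads could not be recovered for most genes. Low genes are limited by depth, as 3 fragments on 1 kb were 0.155 to 0.188 FPKM.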

Other observations

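In this part, the tests of library scaling, of leukocyte content for inflammatory genes and for interferon-stimulated genes against NC and PRP, of monocyte content, of single animals and of abundant epidermal genes were chosen after the result was seen, as were the 6 lists described next. The other tests were chosen before their values were seen.

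Cholesterol synthesis genes were lower in PRP-MNs than in NC (median −0.99, 9 of 20 at least 2-fold lower), in PRP than in NC (−0.34), and in PRP-MNs than in PRP (−0.69) and MNs (−1.14), and were within the random range in MNs against NC (0.12). Oxidative stress genes were higher in PRP-MNs than in NC (1.09), PRP (0.84) and MNs (0.59), and within the random range in PRP (0.05) and MNs (0.49) against NC. The heme oxygenase gene Hmox1 was at 166 FPKM in PRP-MNs and 35.9 FPKM in NC. Hypoxia and glycolysis genes lay above random lists in PRP against NC (0.30), and not in PRP-MNs (0.18) or MNs (0.10) against NC, nor in PRP-MNs against PRP (0.14) or MNs (0.13). Unfolded protein response genes lay above random lists in PRP-MNs against PRP (0.44), and not in PRP-MNs (0.30), PRP (0.14) or MNs (−0.02) against NC, nor in PRP-MNs against MNs (0.27).

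Genes of circulating monocytes and of resident skin macrophages differed in their order across libraries. Monocyte genes had medians of 4.91 in PRP-MNs, 3.42 in PRP and 2.87 in MNs against NC, and in PRP-MNs 2.27 against PRP and 2.85 against MNs. That list holds Ly6c2, Chil3 and Ms4a4c, which had already been seen at the top of the ranking, so it is not independent evidence. Resident macrophage genes were higher in MNs against NC (1.48), were within the random range in PRP-MNs (−0.13) and PRP (0.09) against NC and in PRP-MNs against PRP (−0.22), and were lower in PRP-MNs than in MNs (−1.61). Mrc1 was at 131 FPKM in MNs, 62.4 FPKM in PRP-MNs, 21.6 FPKM in PRP and 9.63 FPKM in NC, whereas Retnla was at 58.7, 7.55, 31.0 and 127 FPKM in the same libraries.

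Inflammatory and interferon genes were highest in PRP-MNs. Library scaling cannot account for this, since 1 factor per library moves all genes alike, and the lower quartile of each list in PRP-MNs against MNs lay at least 1.41 above the upper quartile of all genes. More leukocytes in an unchanged mixture do not account for the whole interferon difference between PRP-MNs and MNs, where the lower quartile of interferon-stimulated genes lay 0.64 above the upper quartile of genes shared by leukocytes, but may account for the differences from NC and PRP, where the same value was −0.33 and −0.42, and for part of the inflammatory difference from MNs (−0.0843). More monocytes stay open for the interferon genes, since the same value for circulating monocyte genes was −0.99, and that list holds genes already seen at the top of the ranking. A difference between animals cannot be told apart from a difference between treatments, since the number of libraries per group was 1.

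Epidermal differentiation genes were lower in both microneedle libraries. In PRP against the same NC library they were also below random lists, by less (−0.85), as were genes shared by epithelia (−0.53). A smaller share of all epithelium would lower all epithelial genes alike. The lower quartile of genes shared by epithelia lay above the upper quartile of differentiation genes by 0.60 in MNs and 0.28 in PRP-MNs. This cannot exclude a smaller share of epidermis alone, since glands and follicles are epithelia too. Sebaceous gland (3.05) and follicle stem cell (1.43) genes were higher in MNs. In PRP-MNs sebaceous gland genes were lower (−2.13). The follicle stem cell median there was −0.00, with 1 of 9 genes at least 2-fold higher and 2 lower. The shared genes were themselves lower (−1.04 and −1.89), so a smaller share of epidermis may account for a part or the whole. A few abundant epidermal genes did not set the scale, as the median after rescaling without hair, epidermal and muscle genes was −2.09 or lower in both. A difference in sampled skin or in treatment stays open and was not tested.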
